A study of Danio rerio with 8 samples.

How the data were processed

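The study measured ribosome footprints in whole zebrafish embryos of the TL/AB strains at 8 stages with 1 library each. Per the labels' protocols, frozen embryos were lysed with cycloheximide, treated with RNase I and passed through a sucrose cushion, and footprints were selected by size on a gel. Per the submitters' processing notes, Bowtie2, TopHat2 and bedtools were used on the Zv9 (danRer7) build. Versions, settings and the order of the tools are not given in the sources used here. No values per library entered the comparisons, so no library was averaged, compared or left out, and 0 columns of per-sample values were passed over.

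The deposited values used here are exon coordinates, the first and last base of each exon counted from 1, in 2 annotation tables that belong to no single library. Every record is an exon and no record carries a score, an expression value or a class. Per the authors' deposited description, the zebrafish models combine the lncRNAs of Ulitsky et al. (linc-) and of Pauli et al. (Zv9), with other developmental transcripts of the latter and RefSeq transcripts from the same loci. The other developmental transcripts carry the Zv9_ prefix too, so they could not be separated from the lncRNAs of that source. The mouse models are lncRNAs of embryonic stem cells (Guttman et al.) with RefSeq models, per the same description. The tool that grouped transcripts into loci is not given in the sources used here. Loci rebuilt from exon overlap on 1 strand numbered 1014 and 167, as many as deposited. Because a locus merges models that share exon sequence, the locus numbers depend on that step. The catalogues were made from different annotations of different samples, so a difference between species cannot be separated from a difference between annotation methods.

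Exon numbers ran in genomic order on both strands for 100% of records, so exons were put in the order of transcription from the strand before first and last exons were named. The transcript with the longest spliced length stood for its locus, and the intron value of a locus was the median of that transcript. Introns shorter than 50 nt numbered 1 of 3115 in zebrafish and 7 of 1330 in mouse and were kept.

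Differences of medians or means between species were tested with two-sided permutation tests (100000 permutations), shares with two-sided Fisher's exact tests, exon positions with sign-flip permutation tests within loci, and strand with exact binomial tests. Loci per chromosome were set against chromosome length with 100000 Monte Carlo draws, and neighbour distances against 10000 random placements, a permutation of positions. Intervals of medians, means and folds are 95% bootstrap intervals from 2000 resamples, and those of shares are exact binomial intervals. They treat loci, or transcripts where every transcript was counted, as independent draws and cover no biological variation. The limit for a share of 0 used 3 counts. The 20 planned tests were adjusted together by Benjamini-Hochberg, and 15 passed 0.05. A further 12 differences, between the zebrafish sources and between species in exon ratios, were added after the data had been seen and adjusted among themselves. The tests, most of the other settings tried and the rule for named loci were set before the data were examined.

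The rule named, per catalogue, the 5 loci with the longest spliced model, the 5 widest, the 5 with the most exons, the 5 with the most transcripts, the 2 longest runs of neighbours within 10 kb, and every locus on a list of 33 entries for known lncRNAs. It gave 24 zebrafish and 16 mouse loci before runs were added, of which the report names the leading ones. Zebrafish names came from the identifiers themselves and from a RefSeq table of the GRCz12tu assembly, used for names only, which matched 26 of 27 RefSeq transcripts. No name table for mouse was used here, so mouse loci appear by identifier. All coordinates are those of the deposited tables.

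The programs were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The length test was tested on simulated data, with lengths drawn from the 1014 zebrafish loci for groups of 1014 and 167 loci. It called 5.5% of 200 simulations with no difference, 60.5% with a fold of 1.2 and 100% with a fold of 1.5. The spacing test, run on 992 loci, called 4.5% of 200 random arrangements and 100% of those with 40 planted pairs. Those arrangements were drawn as the test draws its own placements, so the rate does not cover uneven density along chromosomes. Numbers of planted pairs between 0 and 40 were not simulated. Each simulated test used fewer permutations or placements than the comparisons did. The number of simulations was raised to 200 after a smaller set had given a higher false-call rate for spacing.

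Position relative to coding genes, splice-site and reading-frame content and classes of loci were not analysed here, because no genome or annotation of either build was used and the tables hold no class.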

Results

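Ribosome profiling, the sequencing of the RNA fragments that ribosomes protect from nuclease, was carried out on whole TL/AB zebrafish embryos at 8 stages. The earliest embryos had 2 to 4 cells, the next 256 cells and those after them are labelled 1K cell. Blastula, gastrula and tailbud embryos followed, at the stages named Dome, Shield and Bud, and the oldest were taken at 28 hours and at 5 days after fertilization. Each stage had 1 library, so no stage has a replicate and no difference between stages was tested. Footprint values per library were not analysed here, and the depth of the libraries is therefore unknown. The values analysed were 2 catalogues of long non-coding RNA (lncRNA) transcript models, 1 for zebrafish on the Zv9 build and 1 for mouse on the mm9 build. A locus is a group of models that share exon sequence on 1 strand. The zebrafish catalogue held 1425 transcripts in 1014 loci with 4540 exon records. The mouse catalogue held 395 transcripts in 167 loci with 1725 exon records. Tests below ran across loci, which are not biological replicates. Where every transcript was counted they ran across transcripts, and transcripts of the same locus are not independent. The p-values describe these catalogues only.

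The zebrafish models came chiefly from a pair of earlier annotations, told apart by the start of the identifier. Models whose names begin with Zv9_ alone described 570 loci, and models whose names begin with linc- alone described 405. Both kinds of model described 22 loci, or 2.17% of the catalogue. RefSeq models were present at the remaining 17 loci, 16 of which carried a non-coding RefSeq transcript and 1 a coding one. In mouse, models named linc were present at 159 of the 167 loci, RefSeq non-coding models at 66, models named Novel_ at 24 and RefSeq coding models at 8. What the Novel_ name stands for is not given in the sources used here.

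Of a list of 33 entries for well-known lncRNAs, 4 were found by name in the zebrafish catalogue. The malat1 locus, whose mammalian counterpart is an abundant nuclear RNA, lay at XLOC_003759 on chromosome 14 from 48565580 to 48574855, and its longest model was a single exon of 8571 nt. The cyrano RNA, also called oip5-as1, lay at XLOC_003108 on chromosome 13 from 33484733 to 33491201, with a longest model of 4619 nt in 3 exons. The megamind RNA lay at XLOC_005409 on chromosome 17 from 22517187 to 22519802, with 1 model of 1402 nt in 3 exons. The epb41l4a lncRNA lay at XLOC_001288 on chromosome 10 from 1734816 to 1745335, with a longest model of 5954 nt. Its spelling in the catalogue was added to the list after the names had been seen. Mouse identifiers carried no gene symbols, so the entries were not looked up there. RefSeq non-coding accessions, present at 66 mouse loci, were not matched to names, and listed lncRNAs may be among them.

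Microrna precursors made up 21 of the 27 zebrafish RefSeq transcripts, and they fell in 11 loci, or 1.08% of the catalogue. All 11 loci were described by Zv9_ models and 0 by linc- models. Of the 21 precursors, 20 lay wholly inside an exon of the longer model, and the remaining precursor, mir144, lay partly inside one. A precursor that touched no exon could not have been counted, since a locus groups models that share exon sequence. XLOC_000292 on chromosome 1, from 2804473 to 2807213 on the plus strand, held 6 precursors (mir17a-1, mir18a, dre-mir-19a, dre-mir-20a, dre-mir-19b and mir92a-1). The first of these began at 2806071 and the last ended at 2806953. Its longer model, Zv9_00000127, had 2 exons and a spliced length of 1387 nt. A related locus, XLOC_016116 on chromosome 9 from 55417517 to 55422084 on the minus strand, held mir17a-2, mir18b and mir92a-2. This microRNA family is known for promoting cell proliferation. XLOC_013118 on chromosome 5 held mir144 and dre-mir-451a, microRNAs of the red cell lineage, between 43889617 and 43891656. The muscle microRNAs mir1-2 and mir133a-1 shared XLOC_000230 on an unplaced scaffold, and mir133a-2 lay in XLOC_009451 on chromosome 23. The neural microRNAs dre-mir-9-1 and mir9-3 lay in XLOC_004522 on chromosome 16 and XLOC_010716 on chromosome 25. The remaining precursors were mir15a-2 and mir16c in XLOC_015999, dre-mir-148 in XLOC_015833, mir199-2a in XLOC_011612 and mir219-2 in XLOC_012743. The single coding RefSeq transcript was cyp7a1, which encodes the enzyme that limits the rate of bile acid synthesis, at XLOC_010664 on chromosome 25 from 341199 to 346346. These loci were picked after the names had been seen.

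**Figure D1:**
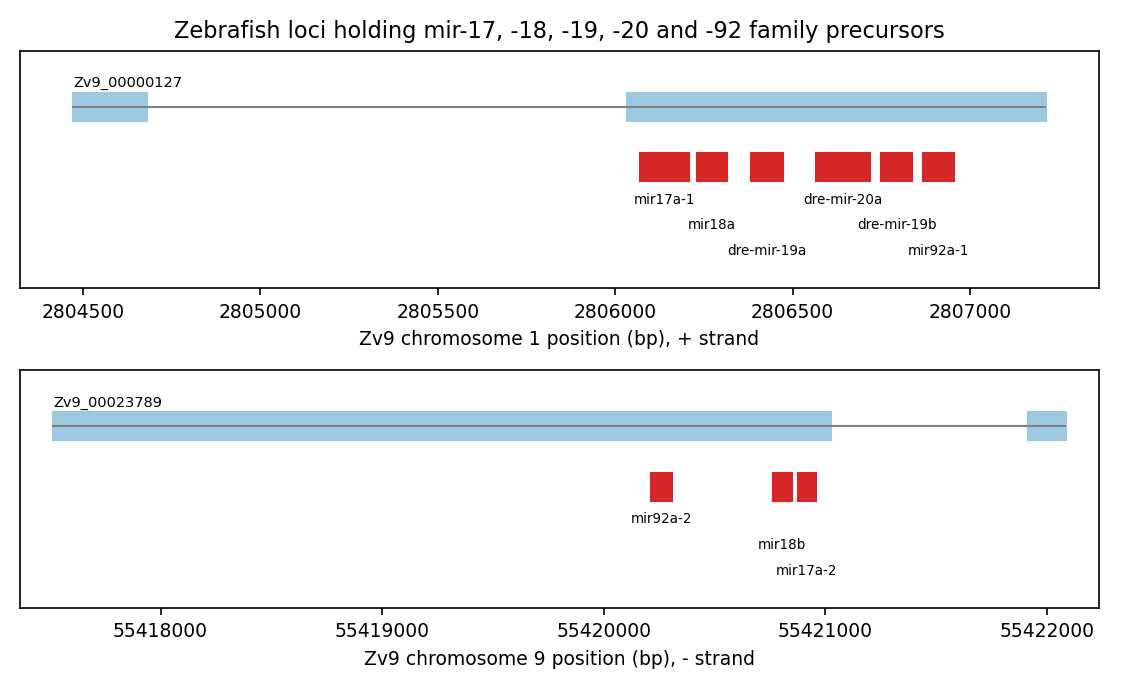
Map of XLOC_000292 on Zv9 chromosome 1 (top) and XLOC_016116 on chromosome 9 (bottom), with position in bp on the horizontal axis. Blue boxes are exons of the longer models joined by their introns, and red boxes are microRNA precursors, 6 in the upper locus and 3 in the lower one, all within an exon.

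The zebrafish and mouse catalogues were compared to ask whether their lncRNA models share a structure. Coding RefSeq transcripts, present at 8 mouse loci, were kept and could stand for a locus. They did so at XLOC_010664 in zebrafish and at XLOC_019254 in mouse, among others not listed here. Zebrafish models were shorter, with a median spliced length of 1163 nt (95% bootstrap interval 1097.5 to 1234) against 1827 nt (1685 to 2178) in mouse. The difference of -664 nt had an interval of -1054 to -501 and a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give (Benjamini-Hochberg adjusted p = 2.2e-05 over 20 tests). Its size depended on the model taken for a locus. With every transcript counted it was -321 nt (1105 against 1426 nt, interval -540 to -141, permutation p = 1e-05), an interval and p-value that overstate the precision because transcripts share loci. With the exons of each locus merged it was -808 nt (1208 against 2016 nt, permutation p = 1e-05). The Zv9_ models alone had a median of 874.5 nt over 606 loci and differed from mouse by -952.5 nt (permutation p = 1e-05). The linc- models of zebrafish had a median of 1702 nt over 429 loci, and against all mouse models they differed by -125 nt (permutation p = 0.39). Set against the mouse linc models alone, a comparison chosen after the data were seen, they differed by -18 nt (interval -342 to 278, permutation p = 0.9), and with multi-exon models of both by -223 nt (interval -510 to 106, permutation p = 0.25). Against the mouse RefSeq non-coding models the whole zebrafish catalogue differed by -189 nt (permutation p = 0.2).

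**Figure D2:**
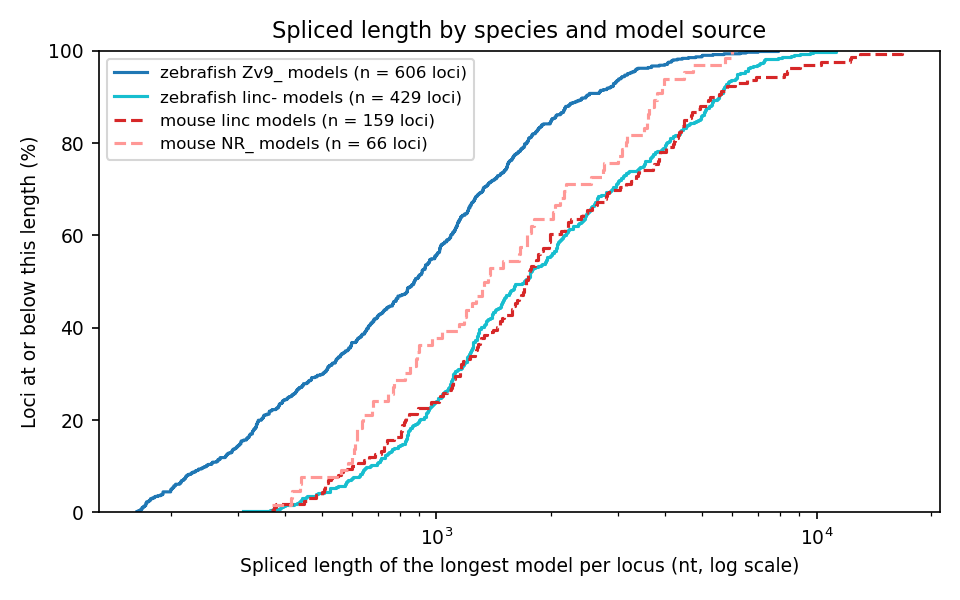
Cumulative share of loci (%, vertical axis) by spliced length of the longest model (nt, log scale, horizontal axis) for the zebrafish Zv9_ and linc- models and the mouse linc and NR_ (RefSeq non-coding) models. The Zv9_ curve lies to the left, with a median of 874.5 nt, while the linc- and linc curves run close together, with medians of 1702 and 1720 nt.

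Zebrafish models also had fewer exons, with a mean of 3.04 ± 2.24 (SD, n = 1014 loci) against 4.25 ± 3.21 (n = 167), and this difference of -1.21 passed the permutation test (p = 1e-05). It held among all multi-exon models, at 3.33 against 4.27 exons (difference -0.942, permutation p = 4e-05), and for Zv9_ models alone, which have no single-exon locus (difference -1.53, permutation p = 1e-05). With linc- and linc models alone the means were 3.45 against 4.16 exons (permutation p = 0.012). The difference between these 2 sources went with single-exon models, since among their multi-exon models alone, a comparison chosen after the data were seen, linc- models had 4.50 exons (n = 301) against 4.16 (n = 159), which turned the direction and did not pass the test (difference 0.331, interval -0.273 to 0.878, permutation p = 0.29). Single-exon models stood for 126 of 1014 zebrafish loci, or 12.4% (exact 95% interval 10.5 to 14.6), and for 1 of 167 mouse loci, or 0.599% (0.0152 to 3.29). The shares differed by Fisher's exact test (two-sided p = 4.9e-08). The linc- models supplied these loci: 128 of the 429 loci they described were single-exon by that source, or 29.8%. None of the 606 Zv9_ loci was, which would allow a share of up to 0.495% if loci were random draws. No single-exon model occurred among the 864 Zv9_ transcripts, nor in mouse among the 208 linc and 80 Novel_ transcripts. Whether these sources leave out single-exon models by rule was not tested. The p-values for single-exon shares may therefore describe the sources only. The malat1 model and linc-tnnt3b_1, the longest model of the catalogue at 11211 nt, were both single exons.

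Zebrafish loci spanned a median of 6800 bp against 10715 bp in mouse (difference -3915 bp, interval -6392 to -993, permutation p = 0.00075). Among multi-exon models the difference was -2329 bp (8404.5 against 10733.5 bp, permutation p = 0.044), with a bootstrap interval of -4878 to 352 that reached 0. Against linc models alone, linc- loci spanned 5727 bp against 9934 bp (permutation p = 1e-05), but multi-exon linc- loci spanned 8496 bp, a difference of -1438 bp that did not pass the test (interval -3869 to 1006, permutation p = 0.089). Zv9_ loci alone did not pass the test against all mouse models (difference -2708.5 bp, permutation p = 0.099). The median intron was longer in zebrafish, at 2473.5 bp over 888 loci against 1486.75 bp over 166 (permutation p = 0.0078). The difference was 2138 bp for Zv9_ models alone (permutation p = 0.00083) and was not past the threshold for linc- models alone (283.75 bp, permutation p = 0.14). More than 1 transcript was listed at 24.8% of zebrafish loci (exact interval 22.1 to 27.5) and at 58.1% of mouse loci (50.2 to 65.7), a difference by Fisher's exact test (p = 7.1e-17). A locus that holds models of more than 1 source has more than 1 transcript by construction. RefSeq non-coding and linc models alone shared 50 of 167 mouse loci, and Novel_ and linc models a further 14. In zebrafish, Zv9_ and linc- models shared 22 of 1014 loci, and RefSeq non-coding and Zv9_ models 13. The p-value therefore reflects, at least in part, the pooling of sources at a locus. Counting linc models alone in mouse, 19.5% of loci had more than 1 transcript, below the zebrafish share by a margin that did not pass the test (difference 5.26 percentage points, Fisher's exact p = 0.16).

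The loci at the extremes differed in source. The 5 longest zebrafish models were all linc- models, among them linc-tnnt3b_1 at XLOC_014239 on chromosome 7, linc-rbl1_1 of 9786 nt at XLOC_013925 on chromosome 6 and linc-prpf4_1 of 9578 nt with 9 exons at XLOC_013210 on chromosome 5. The 5 widest loci were all described by Zv9_ models, led by XLOC_013169 on chromosome 5, which spanned 408125 bp from 54233151 to 54641275 with 2 exons of 1556 nt in all. The most exons in 1 model, 25, were found in linc-wu:fc32f04_1 on chromosome 23 and linc-loc563681_1 on chromosome 7. The most transcripts, 9, were listed at XLOC_004620 on chromosome 16, named after zfpm2a. XLOC_009920 on chromosome 23, which carries the name of the developmental regulator hoxc6a, had 7 transcripts over 166004 bp. In mouse the longest model measured 16710 nt at XLOC_005325 on chromosome 13, from 98252637 to 98285625. The widest mouse locus, XLOC_006861 on chromosome 15, spanned 214417 bp and held 26 transcripts, the most at any locus.

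In both species the last exon was the longest part of models with 3 or more exons. In zebrafish (n = 468 loci) the median lengths were 198 nt for the first exon, 113 nt for the internal exons and 675.5 nt for the last. Within a locus, the last exon was 5.36-fold longer than the internal exons (interval 4.56 to 6.16), in 433 of 468 loci, and 3.59-fold longer than the first exon (2.99 to 4.00), in 379. The first exon was 1.71-fold longer than the internal exons (1.55 to 1.86), in 322 loci. Each of these 3 ratios had a sign-flip permutation p of 1e-05. By source, the first exon was 1.93-fold longer in linc- models (permutation p = 1e-05) and 1.33-fold longer in Zv9_ models (permutation p = 0.00086). In mouse (n = 121 loci) the medians were 187, 140 and 1257 nt. The last exon was 8.16-fold longer than the internal exons (5.66 to 11.8), in 118 of 121 loci, and 5.88-fold longer than the first (4.32 to 7.35), in 105, each with a permutation p of 1e-05. The first mouse exon was 1.24-fold longer than the internal exons (1.05 to 1.43), in 72 loci (permutation p = 0.0074). With the exons of all transcripts of a locus merged, the mouse first exon was 1.14-fold longer and the permutation p was 0.35. The mouse last exon was then 5.55-fold longer than the internal exons (4.02 to 6.91), and 5.46-fold longer (4.49 to 6.92) with every transcript counted. In zebrafish these 2 settings gave 4.93-fold and 4.72-fold. Each of these last-exon ratios had a permutation p of 1e-05. With every transcript counted, transcripts of the same locus entered as separate units, which overstates the precision.

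**Figure D3:**
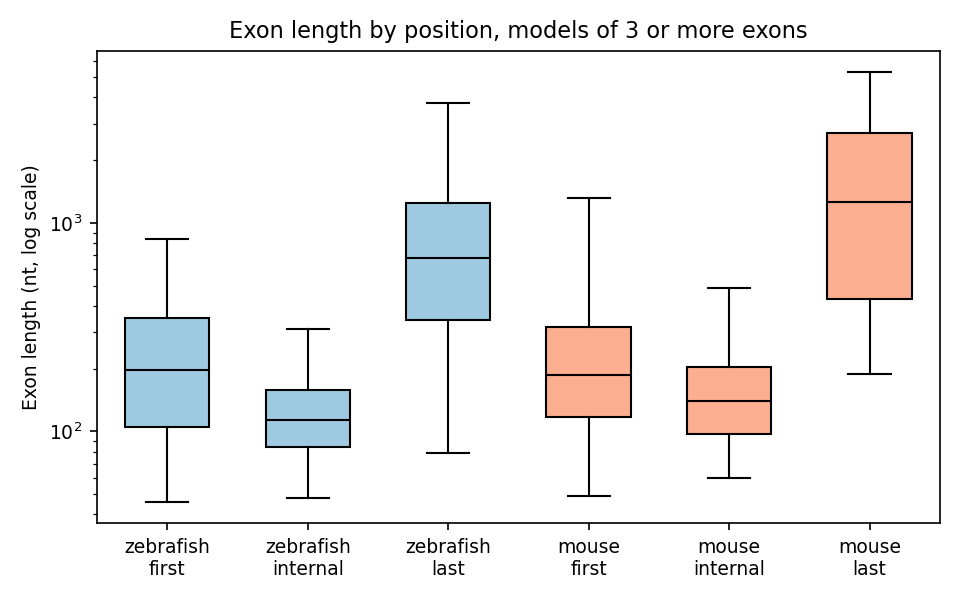
Exon length (nt, log scale) of the first, internal and last exons of the longest model per locus, for 468 zebrafish and 121 mouse loci, with 1 value per locus and position (the median of the internal exons). Boxes span the quartiles with the median as a line, whiskers reach the 5th and 95th percentiles, and the last exons sit highest, with medians of 675.5 and 1257 nt.

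The 992 zebrafish loci on assembled chromosomes departed slightly from chromosome length (chi-square 37.9, Monte Carlo p = 0.036, adjusted p = 0.048). No single chromosome passed its own adjusted test. Chromosome 4 held 63 loci where 46.1 were expected (exact binomial p = 0.015, adjusted p = 0.27) and chromosome 1 held 30 where 44.8 were expected (p = 0.022, adjusted p = 0.27). By source, the overall Monte Carlo p was 0.22 for Zv9_ models (chi-square 29.1, n = 584 loci) and 0.017 for linc- models (chi-square 40.9, n = 429 loci), and the difference between the sources was not tested. Mouse loci gave a p of 0.086. Chromosome lengths were taken from the end of the last locus, since no genome was used here.

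Zebrafish loci lay closer together than random placement gave. A neighbour within 10 kb, or overlapping, was found for 94 of 1014 loci, or 9.27% (exact interval 7.56 to 11.2), against 4.56% over 10000 random placements on the same sequences (range of 95% of placements 2.96 to 6.41, two-sided p = 0.0002, the smallest they can give). In mouse the share was 8 of 167 loci, or 4.79% (2.09 to 9.22), against 0.394% at random (permutation of positions, p = 0.001). These mouse loci formed only 4 pairs, 2 of them overlapping on opposite strands. In both species close loci enter such a count together, so the exact intervals of these shares are too narrow. An overlapping pair on chromosome 13, XLOC_005325 and XLOC_005787, shared the name stems linc1283.2 and linc2096.2 across strands. Technical explanations were not weighed for mouse. Counted apart, a step chosen after the data were seen, 4.64% of zebrafish loci had a close neighbour without any overlap, against 1.41% at random (permutation of positions, p = 0.0002), and 4.64% overlapped another locus, against 3.14% at random (p = 0.062). With overlapping loci merged beforehand the zebrafish share was 4.85% and did not pass the test (permutation of positions, p = 0.71), but the random placements of that setting could still overlap and the merged loci could not. One run of 3 zebrafish loci lay on chromosome 19 between 19200741 and 19248530 and included a pair named after hoxa3a. Another, all on the plus strand, lay on chromosome 14 between 40176952 and 40288333 and carried the names csnk1a1 and zgc:171223. Its middle locus, XLOC_003436, had a Zv9_ model of 2 exons and 316 nt over 106083 bp. It overlapped the other loci of that run, which only it joined.

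**Figure D4:**
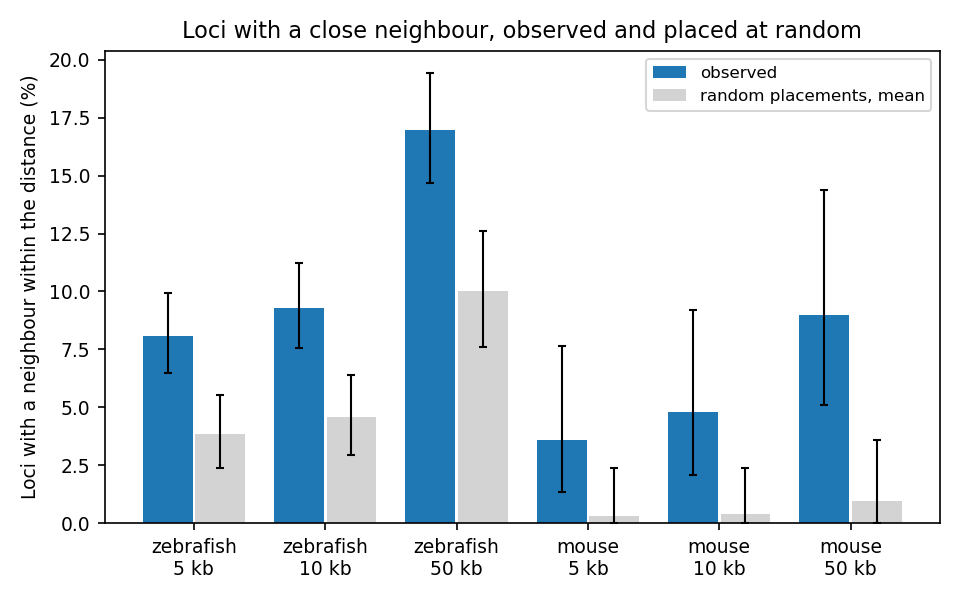
Share of loci (%) with a neighbour within 5, 10 or 50 kb, overlap included, observed (blue, exact 95% intervals) and averaged over random placements (grey, range of 95% of placements). The exact intervals treat close loci as independent and are too narrow. At 10 kb the zebrafish share was 9.27% against 4.56% at random, and the mouse share 4.79% against 0.394%.

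Of 24 zebrafish pairs of close neighbours without overlap, 12 shared a strand (exact binomial p = 1), 10 converged and 2 diverged. The exact interval of the same-strand share, 29.1% to 70.9%, is wide. A further 24 neighbouring pairs overlapped, 15 of them on opposite strands, and exons overlapped in 9 of those 15. Mouse had only 2 close pairs without overlap, too few for any test to pass the threshold. The plus strand held 528 of 1014 zebrafish loci (exact binomial p = 0.2) and 82 of 167 mouse loci (p = 0.88).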

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

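The 12 group differences, the shared-locus test, the linc- against linc comparisons, the exon ratios by source, the same-strand share with overlaps included and the placements within 1 Mb were chosen after the data had been seen, and the multi-exon and single-source tests, planned as other settings, were only then used to weigh explanations. A difference between groups of models was found in 11 of the 12 measures tested, and adjusted p-values are Benjamini-Hochberg values over those 12.

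The 584 zebrafish loci described by Zv9_ models and not by linc- models were set against the 407 described by linc- models and not by Zv9_ models. The Zv9_ minus linc- difference in median spliced length was -844 nt (858 against 1702 nt, interval -1099 to -608, adjusted permutation p = 2e-05). Among multi-exon models it was -663 nt (858 against 1521 nt, adjusted permutation p = 2e-05). The mean number of exons differed by -0.812 over all models (adjusted permutation p = 2e-05) and by -1.82 over multi-exon models (2.73 against 4.55, adjusted permutation p = 2e-05). The share of single-exon loci differed by -28.5 percentage points, from 0 against 28.5% (adjusted Fisher's exact p = 2.4e-49). Whether Zv9_ models could be single-exon was not tested, so that p-value may describe a rule of the source. Zv9_ loci spanned 2083.5 bp more (7928.5 against 5845 bp, adjusted permutation p = 0.013), had median introns longer by 1911.5 bp (3644 against 1732.5 bp, adjusted permutation p = 2e-05) and had more than 1 transcript more often by 6.38 percentage points (24.3% against 17.9%, adjusted Fisher's exact p = 0.02). The span of multi-exon loci did not pass, with a difference of -567.5 bp (interval -2091 to 1345, adjusted permutation p = 0.48).

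Between species, the exon ratios differed on the log10 scale, zebrafish minus mouse. The first-to-internal ratio differed by 0.139 (1.71-fold against 1.24-fold, adjusted permutation p = 0.013), the last-to-internal ratio by -0.182 (5.36-fold against 8.16-fold, adjusted permutation p = 0.0084) and the last-to-first ratio by -0.215 (3.59-fold against 5.88-fold, adjusted permutation p = 0.0046). These differences were recomputed by source and with the exons of a locus merged, in 15 further comparisons without adjustment. The last-to-internal difference was not seen between linc- and linc models (6.48-fold against 6.34-fold, difference 0.00925, interval -0.175 to 0.222, permutation p = 0.92). For Zv9_ models against all mouse models it was -0.264 (4.45-fold against 8.16-fold, interval -0.442 to -0.0804, permutation p = 0.00018), for Zv9_ against linc models -0.154 (permutation p = 0.057) and for linc- models against all mouse models -0.100 (permutation p = 0.16). With merged exons it was -0.0512 (4.93-fold against 5.55-fold, permutation p = 0.44), and with all models its bootstrap interval, -0.367 to 0.000309, reached 0. The first-to-internal difference was 0.203 between linc- and linc models (1.93-fold against 1.21-fold, permutation p = 0.0001). For Zv9_ models against all mouse models it was 0.031 (1.33-fold against 1.24-fold, interval -0.0716 to 0.157, permutation p = 0.56). The last-to-first difference kept its direction and passed the permutation test in the 5 recomputations, from -0.152 (p = 0.031) for linc- against linc to -0.251 (p = 0.001) with merged exons.

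The shorter zebrafish models may follow from the mix of sources. Single-exon models did not account for the species difference. Among multi-exon models it was -770 nt (1049.5 against 1819.5 nt, interval -1103 to -605), no smaller than the -664 nt with all models. The difference of -844 nt between the zebrafish sources is larger than that between species, and linc- models differed from mouse linc models by -18 nt (interval -342 to 278), or by -223 nt among multi-exon models (interval -510 to 106). Whether the sources describe the same RNA at different lengths cannot be told apart from a difference in which RNAs they hold: at the 22 shared loci the linc- model was 1.18-fold as long as the Zv9_ model, longer in 15 of 22, with an interval of 0.938 to 2.03 (sign-flip permutation p = 0.26). No biological explanation was tested, since species and annotation go together in these tables.

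The closeness of zebrafish loci was weighed against 3 technical explanations. A locus entered under both sources was not the whole cause, as 4.20% of linc- loci had a linc- neighbour within 10 kb against 1.36% at random (permutation of positions, p = 0.0054) and 5.61% of Zv9_ loci a Zv9_ neighbour against 3.38% (p = 0.044). Pieces of 1 transcript entered on the same strand were not the whole cause either. Of the close pairs without overlap, 50% shared a strand (exact upper bound 70.9%), below the 84.8% reached if same-strand pieces made their whole excess. With overlaps included, 43.75% of 48 pairs shared a strand (exact interval 29.5 to 58.8), below 75.4% on the same reckoning. That share carries less weight, since same-strand models with shared exon sequence are already 1 locus, which lowers it. Pieces entered on opposite strands cannot be judged from these shares. Exons overlapped in 9 zebrafish pairs on opposite strands. Placing loci within 1 Mb of their own position gave a mean of 5.19% (range of 95% of placements 3.43 to 7.06) against 9.48% of the 992 loci on chromosomes, so uneven density on that scale was not the whole cause. Each may still add to the excess, and the distribution of coding genes, which lncRNA annotations usually avoid, was not tested. No biological explanation was tested.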

How the results depend on the processing

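The tests with linc- and linc models alone (multi-exon ones included), close neighbours without overlap and overlapping neighbours included were chosen after seeing the data; the others were planned. Alternatives were judged on unadjusted p-values. Some that counted as kept lay near 0.05, such as the mouse first-to-internal ratio with linc models (permutation p = 0.049). Of 143 alternatives over 20 results, 100 kept their side of the threshold and their direction (the chromosome chi-square has none), 23 kept the direction but were no longer past it, and 8 reversed. The other 12 concern the same-strand share, which was 50% and so had no direction. The alternatives for that share ranged from 28.6% to 64.7% in zebrafish and from 0 to 55.2% in mouse, and none passed the threshold. Some of the 100 repeat the main values and add no weight. All mouse loci lie on assembled chromosomes, so that setting left mouse spacing and strand balance unchanged. Loci rebuilt from exon overlap likewise gave the main difference in transcripts per locus. Where fewer loci entered (24 for Novel_, 66 for NR_) the smaller number alone lowers the chance of passing. With a single mouse source, the count of transcripts per locus also loses what came from pooling sources. Otherwise the cause was not tested.

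With zebrafish linc- models alone, spliced length differed by -125 nt and introns by 283.75 bp, and the plus-strand share was 48.3%. With Zv9_ models alone, span differed by -2708.5 bp, the single-exon share reversed to -0.599 points and the chromosome chi-square was 29.1. With linc- against linc, the differences were -18 nt in spliced length, 256 bp in introns and -1.78 points in loci with more than 1 transcript; with multi-exon models of both, they were -223 nt and -1438 bp in span, and exons reversed to 0.331. With mouse NR_ models alone, they were -189 nt, -1100 bp in span, 881.5 bp in introns and -10.1 points in transcripts per locus, the first-to-internal log10 ratio was 0.066 and the plus-strand share 51.5%. With mouse linc models alone, transcripts per locus reversed to 5.26 points. With Novel_ models alone, spliced length reversed to 177 nt and span to 1005 bp, exons differed by -0.836, introns by 921 bp and single-exon share by 12.4 points, the log10 exon ratios were 0.171, 0.432 and 0.317, and 0 of 24 loci had a neighbour within 10 kb. This last was counted as a reversal, but random placement gave only 0.0508%, so a count of 0 was near certain and shows none. With the union of exons, the mouse first-to-internal log10 ratio was 0.058. With overlapping loci merged first, 4.85% of zebrafish and 2.42% of mouse loci had a close neighbour; that setting lets random placements overlap but not the merged loci, and close neighbours without overlap alone gave 4.64% and 2.40%, both past the threshold.

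No paired analysis was possible because each stage had 1 library and no values per library were used. Classes of loci, position relative to coding genes, and splice-site and reading-frame content were not run. The depth of the 8 libraries limits nothing here, since none of their reads entered. The depth of the data behind the transcript models was not examined and could limit how complete they are. Zebrafish had 27 loci with a longest model under 200 nt, all described by Zv9_ models, and without them spliced length differed by -624 nt. The 167 mouse loci, and the 24 close zebrafish pairs, limit the precision.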

Other observations

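The identifiers of linc- models carry gene symbols, and several of them belong to families of developmental transcription factors. XLOC_003504 on chromosome 14, from 176793 to 182388, carries a name matched to msx1a and was a single exon of 5596 nt. XLOC_009640 on chromosome 23, from 36237585 to 36242104, carries a name matched to hoxc1a and was a single exon of 4520 nt on the plus strand. It lies within the bounds of XLOC_009920, which carries the name hoxc6a on the minus strand. XLOC_013752 and XLOC_013753 on chromosome 6 both carry names matched to pou3f3b, with longest models of 4095 and 506 nt. XLOC_006268 on chromosome 19, with a name matched to sox4a, had 5 exons and 4104 nt. How a symbol was assigned to a model is not given in the sources used here.

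Of 368 protein-coding symbols matched from 419 distinct names (87.8%), 19 belonged to 27 such family stems, or 5.16% (exact interval 3.14 to 7.95), against 1.29% of 27039 protein-coding genes (odds ratio 4.35, Fisher's exact p = 3.8e-07). Without hox genes it was 14 of 363 (odds ratio 3.69, Fisher's exact p = 6.2e-05). This is the second version of the count. The first matched 78.8% of names, under the 80% needed, and took gatad2b for a gata gene, and it gave odds ratios of 4.42 and 3.82. In both versions the families were picked after the names had been seen, so these p-values carry no independent weight, and the background does not account for the space around each gene. Of the 21 loci with such names, 13 were single-exon by their linc- models, or 61.9% (exact interval 38.4 to 81.9), against 115 of 408 other linc- loci, or 28.2% (Fisher's exact p = 0.0023), under the same limit. All 6 hox loci were single-exon by their linc- models, although XLOC_009920 also held a Zv9_ model of 7 exons. Without the hox loci the share was 7 of 15, or 46.7% (exact interval 21.3 to 73.4), which did not differ from the 28.2% past the threshold (Fisher's exact p = 0.15).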
